A study of Rattus norvegicus with 8 samples.

How the data were processed

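RNA was sequenced from endothelial cells of 2 brain meningeal tissues of untreated Lewis rats, an inbred laboratory strain. Per the labels' protocols, the tissues were digested with Liberase TM and DNase, CD31+ CD45- CD11b- cells were sorted by flow cytometry, RNA was purified with TRIzol, and libraries were prepared with the Illumina TruSeq RNA kit. Per the series' design text, each library pooled 4 animals and each tissue was sampled in 4 biological replicates. The 8 libraries were 4 of dura and 4 of leptomeninges, and groups and replicate numbers were taken from the sample titles.

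The authors deposited one table of raw read counts per library, with an Ensembl rat gene identifier and a whole-number count on each line and no header. The submitters' processing notes name bcl2fastq 2.20, STAR 2.5 and featureCounts 1.5.0-p1 and the genome build rn6. The annotation release, the strand setting, the treatment of multimapping reads and any read filter are not given in the sources used here. Without a stated strand setting, reads of a gene and of an overlapping or antisense gene cannot be told apart, and near-identical gene copies may share or lose reads. All 8 tables held the same 32754 identifiers in the same order, and none held a summary line. The tables were used as deposited.

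The tables give identifiers without gene symbols. The gene table used here lists 47357 rat genes, 0 of them with an Ensembl identifier, so 0 of the 32754 identifiers were matched to a symbol. No name was inferred from an identifier. For this reason the 38 gene lists, their set tests, the counts of list members and the 4 sort genes planned before the data were examined are not analysed here, nor are coordinates, gene lengths or GC content. The planned rule for named genes took, in each direction, the 10 largest log2 fold changes among genes with an adjusted p under 0.05, a mean log2 CPM of 3 or more, no overlap between the 4 values of one tissue and the 4 of the other, and a proper symbol. The last criterion could not be applied, and only the leading 2 identifiers in each direction are described. The rule's parts for members of gene lists and for the sort genes also needed symbols.

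Genes were filtered with filterByExpr at its default settings (a minimum count of 10 and a minimum total of 15), which kept 13458 genes. These held between 99.5% and 99.9% of each library's reads. Counts were scaled by TMM and compared with edgeR 4.0.16 (R 4.3.3), using the quasi-likelihood test with tissue as the only term and all 8 libraries. P-values were two-sided and adjusted by the Benjamini-Hochberg method, and the threshold was an adjusted p under 0.05. Fold changes are log2 values of dura minus leptomeninges. Their standard errors were taken as the size of the log2 fold change divided by the square root of the quasi-likelihood F statistic. Such a value follows from the test and does not measure the error of a fold change where a tissue holds few counts. CPM values, counts scaled to a common total, used the same factors, and log2 CPM values used a prior count of 2. Values of whole libraries were compared with exact two-sided permutation tests over the 70 assignments of 4 libraries to each tissue, which cannot give a p below 0.0286.

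Depth ranged from 13291422 to 34451333 counted reads per library. A count of 3, taken as the floor of detection, corresponded to between 0.0849 and 0.217 CPM. These floors cover counting error only, since reads without molecular identifiers are not independent molecules. The pairs of libraries within a tissue differed far beyond sampling noise, with a chi-square per degree of freedom between 17.3 and 48.5, so no library was treated as a repeat of another.

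The test was run on simulated data with counts drawn for the same genes, library sizes and dispersions, with 200 genes changed. Of 13170 simulated genes tested, edgeR recovered 29.9% of 67 genes changed 1.5-fold, 73.1% of 67 changed 2-fold and 81.8% of 66 changed 4-fold, and 0 recovered genes had the wrong direction. Of its 134 calls in this single simulated draw, 11 (8.21%) were false, a share above the adjusted p threshold of 0.05. DESeq2 made 170 calls on the same simulated counts, 18.8% of them false, and limma-voom made 128, 7.81% of them false. Far fewer genes were changed here than were called in the real data, so these shares do not carry over to the real calls.

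Alternatives fixed before the data were examined were median-ratio, upper-quartile and library-size scaling, no filter on low counts, a stricter filter (over 1 CPM in at least 4 libraries and 100 counts in all), DESeq2 1.42.0, limma-voom (limma 3.58.1) with and without sample weights, robust quasi-likelihood, a test against a 2-fold change, the replicate number as a block, and leaving out each library. A fit without mitochondrial and haemoglobin genes, fixed at the same time, needed gene names and was not run. Leaving out the 10 most abundant genes, thinning every library to 13291422 reads, and leaving out dura replicate 1 and leptomeninges replicate 2 together were added after seeing the data. Genes were also counted per library at thresholds of 1 and 10 counts, before and after thinning. Figures were drawn with matplotlib 3.10.9.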

Results

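Gene expression was measured by bulk RNA sequencing in CD31+ endothelial cells sorted from the dura and from the leptomeninges of the naive rat brain. The dura is the tough outer meningeal membrane beneath the skull, and the leptomeninges are the thin inner membranes, arachnoid and pia, that lie on the brain surface. CD31 is a surface protein of endothelial cells, and the CD45- CD11b- gate was set against leukocytes. There were 4 libraries per tissue, each from 4 pooled animals. Depth was between 13291422 and 34451333 counted reads per library in dura and between 15988636 and 24447082 in leptomeninges, and the mean depths differed by less than the spread between libraries (exact permutation p = 0.857, Benjamini-Hochberg adjusted p = 0.857 over 8 library-level measures). The files name genes by Ensembl identifier, without symbols, so the comparison is given for numbers and levels of genes and for 4 identifiers. Without symbols, marker genes of the sort and of other cell types were not examined, so the purity of the sorted cells was not checked. A difference between the tissues may therefore include RNA of other cells in the sort.

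The first question was whether the libraries grouped by tissue of origin. Over the 13458 tested genes, libraries of different tissues were less alike than libraries of the same tissue. The correlation of log2 CPM was 0.962 ± 0.0116 between leptomeninges libraries (SD over 6 pairs), 0.958 ± 0.00821 between dura libraries (SD over 6 pairs) and 0.875 ± 0.0144 between tissues (SD over 16 pairs). The highest correlation between tissues, 0.897, lay below the lowest within a tissue, 0.945. These are correlations across genes, which are not independent replicates. The first principal component held 60.3% of the variance and separated the tissues. Dura libraries lay between 62.3 and 77.6 on it and leptomeninges libraries between -90.4 and -58.8. The second component held 12.6%, and leptomeninges replicate 2 lay at -63.3 on it while the other leptomeninges libraries lay between 22.8 and 29.6.

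**Figure D1:**
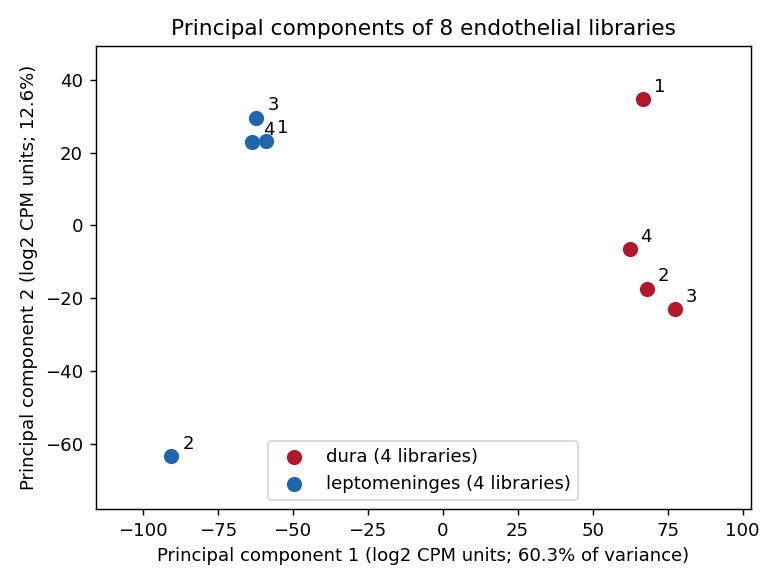
Positions of the 8 libraries on the first 2 principal components of log2 CPM over tested genes, in log2 CPM units, with dura in red, leptomeninges in blue and the replicate number beside each point. The tissues separate on component 1, and leptomeninges replicate 2 lies at -63.3 on component 2, apart from its tissue.

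The main comparison asked which genes differ between endothelial cells of dura and of leptomeninges. Of 13458 tested genes, 4317 (32.1%) differed in edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p under 0.05. Of these, 2134 genes were higher in dura and 2183 higher in leptomeninges. This split depended on the scaling: it was 2177 and 2129 with median-ratio scaling, 2268 and 2053 with upper-quartile scaling, and 2523 and 1794 with library size alone. The other 9141 genes did not pass the threshold. At an unadjusted p under 0.05 there were 5457 genes. Expression did not overlap between the 4 libraries of one tissue and the 4 of the other in 3941 of the 4317 called genes (91.3%) and in 33.9% of all tested genes, where chance gives 2.86%.

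Large changes were more numerous toward dura. Among genes called higher in dura, 1165 of 2134 (54.6%) differed at least 2-fold, 600 at least 4-fold, 314 at least 8-fold and 73 at least 32-fold. Among genes called higher in leptomeninges, 895 of 2183 (41.0%) differed at least 2-fold, 399 at least 4-fold, 207 at least 8-fold and 33 at least 32-fold. The median log2 fold change was 1.10 for genes higher in dura and -0.82 for genes higher in leptomeninges. Without dura replicate 1, 546 genes were called at least 4-fold higher in dura and 485 at least 4-fold higher in leptomeninges. Tested directly against a 2-fold change with edgeR's glmTreat, 670 genes were higher in dura and 534 higher in leptomeninges.

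**Figure D2:**
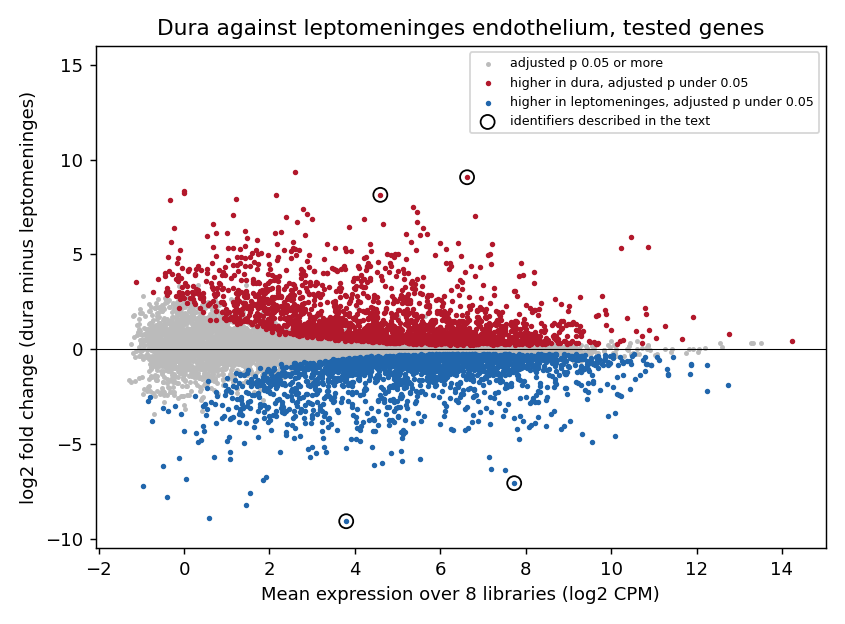
Log2 fold change (dura minus leptomeninges) against mean expression in log2 CPM for the 13458 tested genes. Red and blue points are the 2134 genes higher in dura and the 2183 higher in leptomeninges at an adjusted p under 0.05, grey points did not pass, and circles mark the 4 identifiers described in the text.

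The called genes also made up much of the sequenced RNA. Genes called higher in dura took 27.4 ± 0.0771% of the tested reads in dura (SD, n = 4) and 13.3 ± 0.273% in leptomeninges (SD, n = 4). Genes called higher in leptomeninges took 37.9 ± 0.82% in leptomeninges (SD, n = 4) and 20.5 ± 0.342% in dura (SD, n = 4). The genes at least 4-fold higher in leptomeninges took 6.33 ± 0.0975% there and 0.967 ± 0.0995% in dura (SD, n = 4 each). Those at least 4-fold higher in dura took 4.64 ± 0.0324% in dura and 0.53 ± 0.0691% in leptomeninges (SD, n = 4 each). These genes were chosen by the test on the same libraries, so the shares describe the calls and are not an independent test of them.

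The tested genes were divided into 4 equal bins by mean log2 CPM, and calls in both directions were more frequent in the highest bin than in the lowest. In the lowest bin, 567 of 3365 genes (16.9%) were called, with 11.2% of the tested genes higher in dura and 5.68% higher in leptomeninges. In the highest bin, above a log2 CPM of 5.99, 1555 of 3365 genes (46.2%) were called, with 19.3% of the tested genes higher in dura and 26.9% higher in leptomeninges. Genes higher in dura were thus 66.3% of the calls in the lowest bin and 41.7% in the highest. The median size of a called change was 2.65 on the log2 scale in the lowest bin and 0.66 in the highest. Fold changes are less precise at low counts, where small changes are less likely to be called. The share and the size of called changes therefore both depend on precision, and the sizes do not show larger true changes in weakly expressed genes. Genes called at least 4-fold in either direction were 11.6% of the tested genes in the lowest bin and 5.05% in the highest. The rising share of calls therefore does not mean larger changes in highly expressed genes. Without dura replicate 1, 56.4% of the calls in the lowest bin and 41.6% in the highest were higher in dura. Without leptomeninges replicate 2, the shares were 66.4% and 45.7%. The trend across bins was not tested, since genes are not independent replicates.

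**Figure D3:**
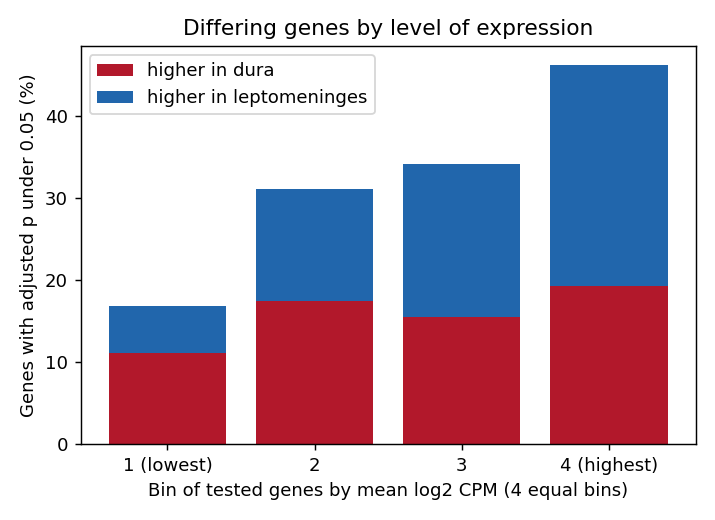
Percentage of tested genes with an adjusted p under 0.05 in each of 4 equal bins of mean log2 CPM, split into genes higher in dura (red) and higher in leptomeninges (blue). The called share rises from 16.9% in the lowest bin to 46.2% in the highest, with genes higher in dura at 11.2% and 19.3% and genes higher in leptomeninges at 5.68% and 26.9%.

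The identifiers described here had the largest fold changes among genes with a mean log2 CPM of 3 or more and no overlap between tissues. ENSRNOG00000020560 was at 197 ± 26.3 CPM in dura and 0.331 ± 0.445 CPM in leptomeninges (SD, n = 4 each). Its log2 fold change was 9.07 ± 0.395 (SE), with an edgeR adjusted p of 5.43e-09. ENSRNOG00000009291 was at 48.1 ± 11.5 CPM in dura and 0.176 ± 0.208 CPM in leptomeninges (SD, n = 4 each), a log2 fold change of 8.14 ± 0.455 (SE) with an edgeR adjusted p of 3.65e-08. The leptomeninges libraries together held 29 counts of ENSRNOG00000020560, 23 of them in replicate 4, and 13 counts of ENSRNOG00000009291. Without leptomeninges replicate 4 the log2 fold change of ENSRNOG00000020560 was 10.77. With each library left out in turn, that of ENSRNOG00000009291 lay between 7.68, without leptomeninges replicate 3, and 8.73, without leptomeninges replicate 2.

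In the other direction, ENSRNOG00000001506 was at 27.6 ± 5.33 CPM in leptomeninges and 0.0547 ± 0.109 CPM in dura (SD, n = 4 each). Its fitted log2 fold change was -9.07 ± 0.516 (SE), with an edgeR adjusted p of 4.13e-08. The dura libraries together held 4 counts of it, all in replicate 2, so this SE does not measure the error of the fold change. The fitted value was -8.44 without dura replicate 4 and -12.22 without dura replicate 2, where 0 counts were left in dura and the fitted value is no bound on the fold. ENSRNOG00000015550 was at 421 ± 226 CPM in leptomeninges and 3.57 ± 4.69 CPM in dura (SD, n = 4 each), a log2 fold change of -7.07 ± 0.732 (SE) with an edgeR adjusted p of 7.6e-06. Without dura replicate 1 the log2 fold change was -8.33. Its level varied widely within each tissue, from 146 to 674 CPM in leptomeninges and from 0.766 to 10.6 CPM in dura, with the highest dura value in replicate 1 and the lowest leptomeninges value in replicate 2.

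**Figure D4:**
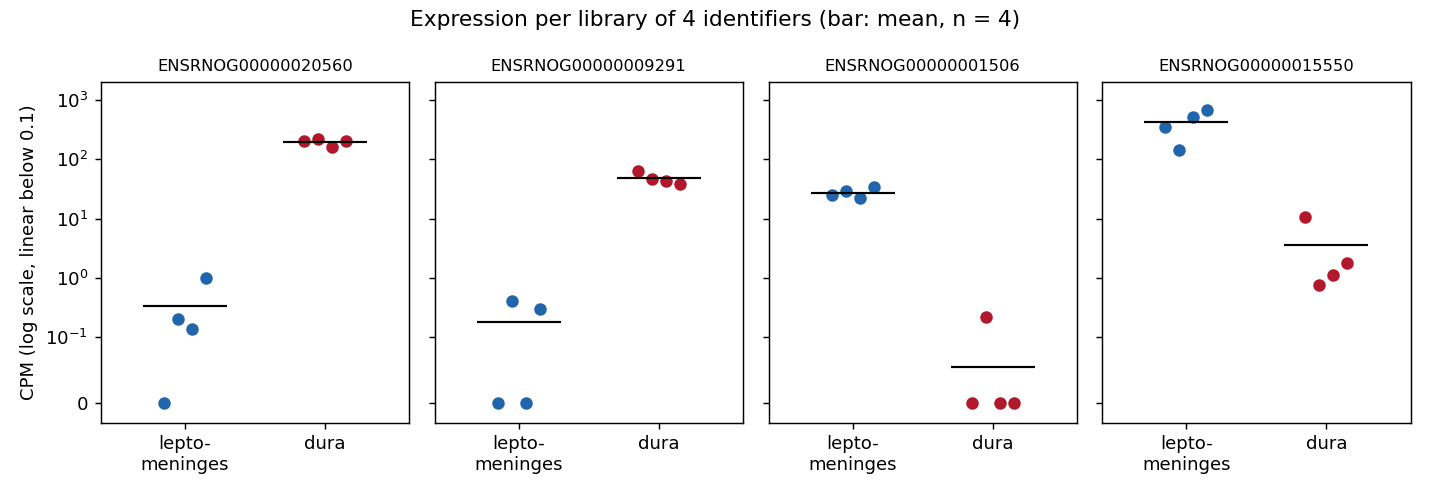
CPM per library of the 4 identifiers, on a scale that is logarithmic above 0.1 CPM and linear below, with the mean of 4 libraries as a bar. The lowest library of the higher tissue is above the highest library of the other in each case, and ENSRNOG00000015550 spans 146 to 674 CPM within leptomeninges.

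The number of genes detected did not separate the tissues. Dura libraries detected 17016 ± 2734 genes at 1 count or more (SD, n = 4) and leptomeninges libraries 16324 ± 1567 (SD, n = 4; exact permutation p = 0.771, adjusted p = 0.857 over 8 measures). The highest value, 21021 genes, came from dura replicate 1, the library with the fewest reads, and the other dura libraries detected between 14915 and 16345. The lowest, 14292 genes, came from leptomeninges replicate 2. At 10 counts or more after thinning, dura libraries detected 13449.5 ± 1354 genes and leptomeninges libraries 12611.2 ± 191 (SD, n = 4 each). The exact permutation p for this measure was 0.114, with an adjusted p of 0.381 over 8 measures. The 10 most abundant genes of each library took 9.78 ± 1.2% of reads in dura and 8.42 ± 0.796% in leptomeninges (SD, n = 4 each; exact permutation p = 0.143, adjusted p = 0.381 over 8 measures). The biological coefficient of variation was 0.27 in dura and 0.248 in leptomeninges. It was 0.241 in dura without replicate 1 and 0.197 in leptomeninges without replicate 2. The median SD of log2 CPM had the opposite order, 0.213 in dura and 0.239 in leptomeninges. Without these libraries it was 0.196 in dura and 0.184 in leptomeninges. Both measures describe the spread between pools of 4 animals, and neither was tested between tissues. With both of these libraries left out, 3993 genes differed between the tissues in edgeR's test, 2026 of them higher in dura and 1967 higher in leptomeninges.

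**Figure D5:**
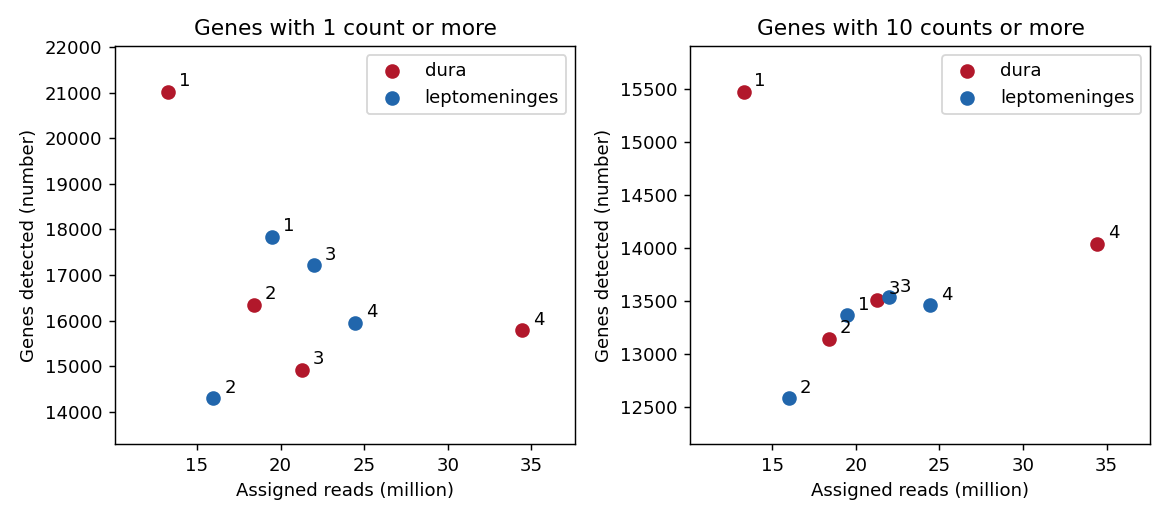
Number of genes with 1 count or more (left) and 10 counts or more (right) against counted reads per library, with dura in red, leptomeninges in blue and the replicate number beside each point. Dura replicate 1 has the fewest reads, 13291422, and the most genes in both panels, 21021 and 15477.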

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

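The tests of deeper sequencing and of dura carry-over, with the bounds set for them, were chosen after the values they measure had been seen, thinning was added after seeing the data, and the tests of an equal addition and of a cell type present in all dura libraries were devised after the first results on dura replicate 1. In 36 sets of 4 libraries of one tissue, 7 had a library far enough from the other 3 to pass the critical value of Dixon's test, where chance gives about 1 in 20. The 36 sets are not independent, since several measure related properties of the same libraries. For ENSRNOG00000001506, among the 7, the other dura libraries were at 0 CPM, so any count would have passed and that flag carries no weight. The design names no group within a tissue, so apart from the cell types weighed here no biological explanation was tested for a single library.

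Dura replicate 1 stood apart in the number of genes with 10 counts or more at a common depth, with 15477 against 12684 to 12866 in the other dura libraries. Deeper sequencing is argued against, since the next smallest dura library had 5100845 more reads than this one. Its reads in 4278 genes without counts in the other dura libraries had a median of 5 counts, with 2.04% of them in the 10 leading genes. That share was under the bound set against cells of a type absent from the others. It cannot decide this, since the share falls with the number of genes. In the other dura libraries, with 213 to 404 such genes, it was 9.2% to 22.4%. Genes of an absent cell type with a stray read elsewhere were also left out. The mean excess was 4.54 times as high in weakly expressed genes as in the 14730 genes silent in the other dura libraries. That ratio was over the bound set for an equal addition, but it cannot decide this either. Only 23484 of the 32754 identifiers had a count in any library, and the rest all counted as silent, which lowered the mean there. Diffuse background, including an equal addition, cells of a type absent from the others and cells of a type present in all dura libraries cannot be told apart. The excess of 2611 genes at 10 counts or more, meant as a test of background, is the pattern itself and decides nothing. Gene lengths were not used. In this library 6 genes were at 10 CPM or more and at least 4-fold above each other dura library, against at most 4 for the others.

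Leptomeninges replicate 2 stood apart in its mean correlation with its own tissue, 0.952 against 0.964 to 0.966, and at -90.4 on the first and -63.3 on the second principal component. It lay farther from dura than the other leptomeninges libraries, which lay at -63.5 to -58.8 on the first. More carry-over of dura cells into this library than into the others is argued against, since genes called higher in dura had a median log2 deviation of -0.131 from the other 3 libraries. Over genes called at least 4-fold higher in dura the median was -0.652, with 71.3% of these genes below the mean of the other 3. The calls included this library, and its position on the first component already implied this sign. Fewer reads in low-count genes is argued against as the whole cause: over 3343 genes with a mean log2 CPM of 6 or more its mean correlation with the other 3 was 0.964, below the lowest among those 3, 0.973. A difference in the mix of sorted cells or in library handling was not tested and remains open.

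The number of genes differing between tissues was tested against other groupings of the libraries. Of the 35 splits of 8 libraries into 4 and 4, only 1, the real one, gave as many as 4317 genes. The highest other split gave 0 by edgeR and 0 by limma-voom. A share of 1 in 35 is the lowest this test can give, so the test argues against chance but cannot exclude it. Every other split mixes the tissues, which widens the spread within its groups. The 0 calls of these splits therefore say little about how far 4317 lies from chance. At an unadjusted p under 0.05 the other splits gave 80 to 897 genes, against 5457 for the real one. A difference in library size is argued against as the cause, since 4248 genes were called with every library thinned to the smallest total.

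Genes called at least 4-fold higher in leptomeninges took 1.12% of tested reads in dura replicate 4, against 0.903% to 0.926% in the other dura libraries. ENSRNOG00000001506 was at 0.219 CPM in dura replicate 2, from 4 counts, and at 0 counts in the other dura libraries. ENSRNOG00000015550 was at 10.6 CPM in dura replicate 1, against 0.766 to 1.81 CPM in the other dura libraries.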

How the results depend on the processing

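Alternatives chosen after seeing the data were thinning to a common depth (4248 differing genes), leaving out the 10 most abundant genes (4310), leaving out dura replicate 1 with leptomeninges replicate 2 (3993), the expression bins after thinning or without either of these libraries, and the alternative settings of detection and of library similarity. The number of differing genes, 4317, fell to 1204 in the test against a 2-fold change, 670 of them higher in dura and 534 higher in leptomeninges, because that test asks for a larger difference. Over the other alternatives run it lay between 3761 without leptomeninges replicate 4 and 4811 with sample weights in limma-voom, and DESeq2 called 4647. Among the 4317 genes, 0 changed sign under the alternatives run, though some were no longer called. Of these calls, 389 were lost with library size alone. Between 422 and 671 were lost with a single library left out, and 705 without dura replicate 1 and leptomeninges replicate 2. Scaling by library size alone moved the share of calls higher in dura from 49.4% to 58.4%. The deviations of same-numbered libraries correlated across genes at 0.112, 0.144, 0.00263 and -0.00439 for numbers 1 to 4, against -0.161 to 0.101 between different numbers. The 4 libraries numbered 1 and 2 correlated best with their own number and the other 4 did not, so the data do not show pairing for all numbers. The deposited names of same-numbered libraries share digits that may be a date, but the labels state no shared day. With the replicate number as a block, 4400 genes were called, 4107 of them shared with the fit without it. The fold changes of the 4 identifiers moved with single libraries and with the method. In limma-voom with sample weights the log2 fold change was 9.52 for ENSRNOG00000009291 and 10.51 for ENSRNOG00000020560. The 4 identifiers kept their direction and an adjusted p under 0.05 (edgeR, limma or DESeq2) in all 22 alternatives. The highest adjusted p was 0.00205, for ENSRNOG00000015550 in the robust quasi-likelihood test. The first principal component held 40.5% of the variance with no filter on low counts and 67.9% with the stricter filter. The mean correlation between tissues was 0.944 with no filter, against 0.968 within tissues, and 0.856 with the stricter filter. The gene list tests and their alternatives, and the fit without mitochondrial and haemoglobin genes, were not run because identifiers were not matched to symbols. After thinning, 13.6% of the calls in the lowest expression bin were lost, where 2844 of 3365 genes were still tested, and 2.83% of those in the highest. Calls were also gained, with 54 gained against 77 lost in the lowest bin and 39 gained against 44 lost in the highest.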

Other observations

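The counts of genes per library given here were chosen after the values of dura replicate 1 and leptomeninges replicate 2 had been seen. Dixon's test was applied to the log2 CPM of every tested gene within each tissue. Leptomeninges replicate 2 was the library past the critical value in 469 genes (3.48%), against 106 to 147 genes for the other leptomeninges libraries. Chance gives 1.25% per library for normally distributed values. That rate is only nominal here, since a gene without counts in the other libraries of its tissue passes at any count. Among dura libraries the numbers were 246 for replicate 1, 172 for replicate 2, 220 for replicate 3 and 113 for replicate 4. Dura replicate 1 held counts in 4278 genes without a count in any other dura library, and the other dura libraries held 404, 213 and 298 such genes. Those 4278 genes together took 0.222% of the reads of dura replicate 1, and 972 of them had 10 counts or more.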
